A study of Rattus norvegicus with 4 samples.

How the data were processed

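Single-cell RNA sequencing was run on CD11b-positive cells from the spinal cord of female Lewis rats. Per the labels' protocols, the animals were uninjured (naive) or had a cut of the dorsolateral quadrant of the cervical cord. Injured cords were taken 8 days after surgery (acute) or 60 days after surgery (chronic). Chronic animals had received lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor 4, or saline, 3 days before the cord was taken. From injured animals a cord section of 2 cm around the lesion was taken, while no section is given for naive animals. Tissue was dissociated mechanically in the cold, myelin debris was removed, and live nucleated CD11b-positive cells were sorted. Each of the 4 groups is 1 library, and the number of animals behind a library is not given in the sources used here.

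The authors deposited, for each library, a matrix of UMI counts per gene and cell barcode, with text tables of barcodes and genes that hold no measurements (unit other). Per the labels, libraries were made with the 10x Genomics 3' chemistry. Per the submitters' processing notes, Cell Ranger 3.0.0 was used. Per the names of the deposited files, the counts had passed through CellBender, which removes background RNA and empty droplets; its version and settings, the genome build and the gene annotation are not given in the sources used here. Background removal can lower or remove UMIs of abundant genes in cells that do not express them, and its strength can differ between libraries. The values are whole-number counts, and the 4 matrices share 23139 features, which pair with 22943 different symbols, 3755 features having no gene symbol. Fixed gene names missing under their own symbol were looked up among the synonyms of the RefSeq table for the rat assembly GRCr8, which was used for names alone; this matched Ank to Ankh, Chil3 to Chi3l3, Il4ra to Il4r and Fcrls to Fcrl2.

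The deposited barcodes numbered 4638 (naive), 17446 (acute), 1617 (chronic saline) and 11125 (chronic LPS). Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored with Scrublet through scanpy 1.11.5. Scrublet's own threshold was used in the naive library, where it removed 1 cell, and in the chronic saline library, where it removed 3. In the acute and chronic LPS libraries that threshold marked under 0.5% of over 5000 cells, so the highest scores were removed instead, at a rate of 0.8% for every 1000 cells, which took out 1687 acute cells (11.6%) and 713 chronic LPS cells (7.55%). Doublet removal therefore acted unequally on the 4 libraries. The cells kept numbered 3510, 12833, 1363 and 8727 in the same order of groups.

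Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells of all libraries were clustered together by the Leiden method (leidenalg 0.10.2) with 15 neighbours at resolution 1 and no batch integration. Clusters were named from marker lists fixed before the data were examined, which was also when the gene lists, the rule for named genes, the comparisons and the other settings to be tried were fixed. How the markers were scored was settled afterwards. A cluster needed at least 3 detected markers and no surplus of another class's markers among its 10 leading genes, and a marker that one of the fixed microglial gene lists also holds (Gpnmb, for example) decided for neither class. A cluster whose cells had a median depth under 1/3 of the median of their library and none of its own class's markers among those 10 genes also stayed unnamed; a shallower cluster with 1 such marker was named microglia-like. Under these thresholds 2 clusters stayed unnamed, one of shallow cells led by Spp1 and one led by T cell and NK cell genes. Classes with at least 50 cells in both groups were compared.

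Within a class, UMIs were summed per library and given as CPM (UMIs of a gene scaled to a common class total). Ratios are log2 of the CPM ratio, with the exact conditional binomial interval of the 2 counts at 95%. Where a library had fewer than 3 UMIs, the ratio was taken against a floor of 3 counts in that library and is called a bound. A lower bound below 0 or an upper bound above 0 gives no direction, and a gene whose bound lies within 2-fold is left open by it. For each of 25 fixed gene lists the median log2 ratio of members with at least 10 UMIs over both libraries was taken, with an order-statistic interval at 95%, the numbers of members at least 2-fold higher or lower, and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The lists are homeostatic microglia; phagocytic and lipid-handling (disease-associated) microglia; type I interferon response; inflammatory cytokines and chemokines; NF-kappaB and Toll-like receptor signalling; MHC class II; MHC class I; complement and Fc receptors; cell division; alternative activation and repair; glycolysis; oxidative phosphorylation; cholesterol synthesis and export; lysosome; iron handling; dissociation and immediate early response; acute phase and antimicrobial genes; markers of neutrophils, monocytes or macrophages, myelin and oligodendrocytes, astrocytes, neurons, lymphocytes and erythroid cells; and mitochondrial transcripts as a sign of RNA quality. Named genes in microglia-like cells were, among genes of at least 100 CPM in the higher library, the 10 highest and 10 lowest by the interval bound nearer to no difference, without mitochondrial, ribosomal protein and haemoglobin genes and entries without a symbol. To these were added up to 4 members of each list, namely the 2 most abundant and the 2 with the largest ratio. In other classes the 5 highest and 5 lowest genes were taken.

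With 1 library per group no test between groups was possible, and no p-value is given. Intervals of ratios, CPM and shares cover counting error only, and those of list medians the spread over member genes, which are not independent. Neither kind covers differences between animals or between library preparations. The intervals of ratios and CPM also leave out the uneven spread of UMIs over cells. The ratio step was tested on simulated counts drawn from the real means and totals with some genes changed by known folds. For chronic LPS over chronic saline, run on 11771 genes, it recovered the direction of 99.0% of 98 genes changed 2-fold and of 100% of 90 genes changed 4-fold, and 96.2% of the intervals held the true ratio. For acute over naive, run on 12587 genes, it recovered 98.9% of 92 genes changed 2-fold. The simulated counts were drawn for class sums and hold no uneven spread over cells. The share of intervals that held the true ratio therefore follows from the design. It does not show how well the intervals cover real data, where few cells can hold most UMIs of a gene. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs and leaving out shallower cells.

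Other settings tried were a stricter cell filter (1000 UMIs, 500 genes, 5% mitochondrial), doublets kept, Leiden resolutions 0.5 and 2, each library clustered alone, totals without mitochondrial and ribosomal protein genes, median-ratio scaling over genes with at least 50 UMIs, an equal-weight mean over cells, thinning to 1000 UMIs, a list minimum of 50 UMIs, and, for the comparison of ratios, a minimum of 200 UMIs and other numbers of leading genes. Leaving out the microglia-like cluster led by Spp1, Igf1 and Gpnmb, or the shallow microglia-like cluster, was added after the data had been seen. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.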

Results

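CD11b-positive myeloid cells of the rat spinal cord were profiled by single-cell RNA sequencing in 4 states, with 1 library each: uninjured (naive), 8 days after a cut of the dorsolateral cervical cord (acute), 60 days after the cut with a saline injection 3 days before collection (chronic saline), and 60 days after the cut with an injection of LPS 3 days before collection (chronic LPS). The libraries held 15917599 UMIs in 4638 barcodes (naive), 77610017 in 17446 (acute), 7368259 in 1617 (chronic saline) and 40178144 in 11125 (chronic LPS). After filtering, 3510, 12833, 1363 and 8727 cells remained, with median depths of 3836, 3470, 4484 and 3140 UMIs per cell. Median mitochondrial shares were 3.02%, 4.77%, 2.94% and 3.68%, and median ribosomal protein shares 8.50%, 12.9%, 9.98% and 13.7%. No group has a second library, so no difference given here has a replicate check. Intervals, at 95%, cover counting error for genes and shares, and the spread over member genes for list medians.

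Microglia-like cells made up most of every library. Their share was 87.5% (exact binomial interval 86.3 to 88.5) in the naive cord, 94.5% (94.1 to 94.9) in the acute, 81.8% (79.7 to 83.8) in the chronic saline and 88.7% (88.0 to 89.3) in the chronic LPS library. Neutrophil-like cells, led by S100a8 and S100a9, were 6.68% (5.41 to 8.13) of cells in the saline library. They were 1.79% (1.52 to 2.09) in the LPS library, 0.826% (0.554 to 1.18) in the naive and 0.226% (0.151 to 0.324) in the acute library. Border-associated macrophage-like cells, the Mrc1-expressing macrophages of meninges and perivascular spaces, were 0.873% (0.719 to 1.05) of acute cells and 4.99%, 5.36% and 5.08% of naive, saline and LPS cells. Monocyte or macrophage-like cells were 3.08% (2.53 to 3.70) of naive, 0.499% (0.384 to 0.636) of acute, 3.60% (2.67 to 4.73) of saline and 1.32% (1.09 to 1.58) of LPS cells. Fibroblast or mural-like cells were 2.62%, 0.179%, 0.954% and 0.940% in the same order. The CD11b sort, the unequal doublet removal and the number of cells loaded can all set these shares. Clusters left unnamed held 1.03%, 3.73%, 1.61% and 2.19% of cells. Clustering each library alone left no acute monocyte or macrophage-like cluster and gave border-associated macrophage-like shares of 1.36% in the acute and 7.70% in the saline library. The stricter cell filter gave an acute monocyte or macrophage-like share of 0.779% and an acute neutrophil-like share of 0.390%.

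**Figure D1:**
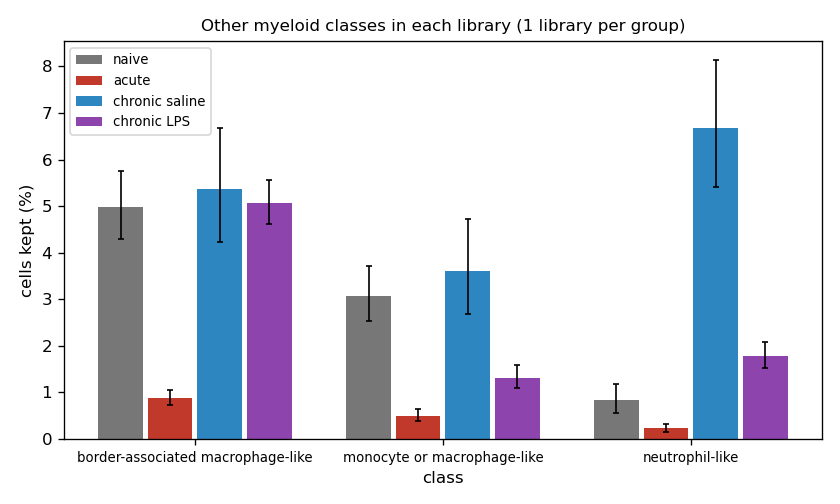
Share of kept cells (%, vertical axis) in 3 other myeloid classes (horizontal axis) for the 4 libraries, with exact 95% binomial intervals as bars. The neutrophil-like share is highest in the chronic saline library (6.68%), and all 3 classes are lowest in the acute library.

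Chronic LPS was compared with chronic saline to see what an inflammatory stimulus adds in microglia of the chronically injured cord. In microglia-like cells of the LPS library the immune genes that LPS is known for were mostly not higher. Of 27 type I interferon genes, 7 were at least 2-fold lower, all 22 NF-kappaB and Toll-like receptor genes stayed within 2-fold, and the purinergic receptor P2ry12, a marker of resting microglia, was lower (1578 against 2488 CPM, 1.58-fold). The genes highest in the LPS library were Odc1, the rate-limiting enzyme of polyamine synthesis (106 against 24.2 CPM, 4.40-fold, but 1.56-fold in cells thinned to 1000 UMIs), and genes of phagocytic microglia such as Igf1, a growth factor (380 against 202 CPM, 1.88-fold, but 1.20-fold thinned), and Spp1, the secreted matrix protein osteopontin (1042 against 561 CPM, 1.86-fold). The lowest were Slfn4, an interferon-responsive Schlafen gene (27.0 against 103 CPM, 3.81-fold lower), and Zfp36, an mRNA-decay factor that restrains cytokine transcripts (84.3 against 209 CPM, 2.48-fold lower). These values rest on 7740 LPS cells and 1115 saline cells with 28739122 and 5204594 UMIs.

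Of the 27 interferon genes measured, 7 were at least 2-fold lower in the LPS library, 20 lay between and none was 2-fold higher. Their median log2 ratio was -0.45 (-0.96 to -0.27), at percentile 0 of matched random lists. Ifit3, an antiviral protein, was 2.97-fold lower, and Usp18, which removes the ubiquitin-like modifier ISG15, was 2.80-fold lower (log2 -1.48, -1.88 to -1.08). The more abundant Ifi27 and Bst2 were closer, at log2 -0.22 and -0.31. Ifit3, Slfn4 and, of the phagocytic genes below, Lgals3 are at least 5-fold higher in neutrophil-like than in microglia-like cells of the saline library, which also has the larger neutrophil-like share. In neutrophil-like cells the interferon median was -0.98 (-1.56 to 0.14), and in border-associated macrophage-like cells 0.24 (0.01 to 0.41). Without the 5% of microglia-like cells highest for the list, the median was -0.25 (-0.40 to 0.04).

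Homeostatic genes had a median of -0.30 (-0.37 to -0.03), with all 21 members within 2-fold. Cst3 (log2 -0.37), a protease inhibitor abundant in microglia, was lower like P2ry12, while Sparc, an extracellular matrix protein, was level (-0.02). The disease-associated list had a median of 0.24 (0.10 to 0.46, percentile 100 of random lists), with 2 of 25 members at least 2-fold higher and 23 between. Lpl, which releases fatty acids from lipoproteins, was 2.73-fold higher (34.6 against 12.7 CPM), Lgals3, a galectin of phagocytic cells, 1.71-fold, Gpnmb, a glycoprotein of lipid-laden macrophages, 1.61-fold, and Apoe, the main lipid carrier of the brain, 1.37-fold. This excess was smaller under other settings. With cells thinned to 1000 UMIs the list median was 0.09, and the ratios of Odc1, Igf1 and Gpnmb were 1.56, 1.20 and 1.02; with the stricter cell filter the list median was 0.05 and the ratios of Odc1 and Gpnmb 2.14 and 1.01. Without the cluster led by Spp1, Igf1 and Gpnmb, the ratio of Igf1 was 1.25.

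Of 19 inflammatory genes, 2 were at least 2-fold higher, 4 at least 2-fold lower and 13 between, with a median of -0.22 (-0.82 to 0.40). Ccl5, a chemoattractant of T cells, had 16.8 CPM in the LPS library and no UMI in saline microglia-like cells, so it was at least 29.1-fold higher; its CPM in saline border-associated macrophage-like cells was at least 5 times higher than in microglia-like cells. Cxcl2, a neutrophil chemoattractant, was 5.57-fold higher at 4.28 CPM (log2 2.48, 1.08 to 4.38), whereas Ccl4, a chemoattractant of monocytes, was 1.77-fold lower (109 against 194 CPM). Ch25h, which makes the oxysterol 25-hydroxycholesterol, was 2.37-fold lower and the transcription factor Cebpb 1.80-fold lower. Cxcl2 is at least 5-fold higher in LPS border-associated macrophage-like cells and Cebpb in monocyte or macrophage-like cells of both libraries. The NF-kappaB and Toll-like receptor list had a median of -0.17 (-0.52 to -0.03), with 22 of 22 within 2-fold, Tlr2 at log2 -0.32 and Ly96, the LPS co-receptor MD-2, at -0.72. Serping1, the inhibitor of complement C1, was 7.87-fold higher (40.9 against 5.19 CPM) within a complement list that otherwise lay between (median -0.07, 1 of 17 higher), and is at least 5-fold higher in fibroblast or mural-like cells of that library.

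The median over all 7472 genes was -0.11. MHC class II genes had a median of -0.11 (-0.26 to -0.01) with 12 of 13 within 2-fold and 1 left open by its bound, and this median was 0.00 under median-ratio scaling. MHC class I stood at -0.21, with 1 of 15 lower. Cell division was at -0.30 (-0.58 to -0.06), with 1 of 19 higher and 1 lower, and alternative activation and repair at -0.27, with 1 of 14 lower. Glycolysis (-0.06, 16 of 16 between), oxidative phosphorylation (-0.10, 1 of 19 lower), cholesterol (0.01, 18 of 18 between), lysosome (-0.09, 20 of 20 between) and iron handling (-0.13, 1 of 11 higher and 1 lower) are given for comparison. The dissociation list stood at -0.08 (1 of 16 lower, Zfp36) and the acute phase list at 0.02 (1 of 11 higher, 2 lower). Mitochondrial transcripts, a sign of RNA quality, had a median of 0.28 (-0.12 to 0.39), all 13 within 2-fold. Markers of other cells in microglia-like cells had medians of -0.20 for neutrophils (8 genes), -0.02 for monocytes (11; 0.49 without 3 members whose bound has no direction), 0.13 for myelin (9), 0.41 for astrocytes (7), -0.88 for neurons (7) and 0.38 for lymphocytes (10, of which 9 at the floor in 1 library). Erythroid markers stood at 7.63, because of haemoglobin UMIs that lay almost wholly in 1 LPS cell.

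Among the rest of the 10 lowest genes, H3f3c (2.94-fold, at least 5-fold higher in monocyte or macrophage-like cells), the MHC class I gene RT1-CE2 (2.64-fold), Gng5 (2.43-fold), Ppial4d (2.05-fold) and the chaperone Pdia4 (1.91-fold) were lower in the LPS library. The 10 lowest genes had a median log2 ratio of -1.26 in microglia-like cells and of -0.95 in border-associated macrophage-like cells. In the latter 9 of 10 were also lower, Cebpb with an interval that includes 0, and Ccl4 was higher (log2 0.50, 0.09 to 0.93). In neutrophil-like cells 8 of the 9 measured were lower, with a median of -1.38. The highest genes also held the ribosomal scaffold Rack1 (1.71-fold), the translation factor subunit Eif3f (1.57-fold), Oscp1 (1.85-fold), Cox7a2l (1.55-fold) and the lysozyme Lyz2 (1.56-fold, at least 5-fold higher in border-associated macrophage-like cells). The ratio of Lyz2 was 1.26 without the cluster led by Spp1, Igf1 and Gpnmb. Of the 10 highest genes, 7 were also higher in border-associated macrophage-like cells, Odc1 with an interval that includes 0. Spp1 (log2 -1.09), Gpnmb (-1.42) and Lgals3 (-0.42) were lower there, with intervals below 0. No cluster held over 50% of the class in either library: clusters 0, 2 and 1 held 40.8%, 14.2% and 12.9% of saline microglia-like cells, and 19.4%, 24.6% and 32.3% of LPS ones. Cluster 14, of shallow cells (median 676.5 UMIs, median ribosomal share 0.615%), held 10.0% of saline and 11.2% of naive but 0.504% of LPS and 0.520% of acute microglia-like cells.

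Border-associated macrophage-like cells (443 LPS and 73 saline cells) differed most in Cxcl13, a B cell chemoattractant, at 1609 CPM (1568 to 1651) against 87.8 (68.7 to 110), or 18.3-fold. Sod2, the mitochondrial superoxide dismutase (3.67-fold, at least 5-fold higher in saline neutrophil-like cells), Igsf6 (2.68-fold) and the complement genes C3 (2.46-fold) and C6 (2.40-fold) were also higher with LPS. Lower were the galectin Lgals1 (4.79-fold), the chemokine receptor Ccr2 (4.07-fold), the protease Napsa (3.19-fold), S100a11 (3.18-fold) and H3f3c (3.06-fold). Ccr2, Napsa, S100a11 and Lgals1 are at least 5-fold higher in another class of the LPS library. At resolution 2 the class held 62 saline and 433 LPS cells. An NK cell-like cluster with Ccr2 and Crip1 among its leading genes then held 14 and 25, against 3 and 12 in the unnamed T and NK cell cluster of resolution 1. Whether such cells add to the saline levels of these genes was not tested. MHC class II genes had a median of -0.67 (-1.11 to -0.31), with 3 of 13 at least 2-fold lower, and cell division genes 1.59 (-0.08 to 3.05), with 10 of 19 higher but 11 at the floor. The 5 highest genes of neutrophil-like cells in the LPS library (156 LPS and 91 saline cells) were led by a defensin. The defensins Defa5 (4.65-fold) and RatNP-3b (3.69-fold), Lcn2, which binds bacterial siderophores (3.49-fold), Ngp (3.24-fold) and Ifitm6 (3.77-fold) were higher. Irf7, the interferon regulatory factor (9.76 against 120 CPM, 12.3-fold), Slfn4 (10.3-fold), Ifit3 (4.94-fold), Stfa2l2 (4.93-fold) and RT1-T24-1 (3.87-fold) were lower.

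**Figure D2:**
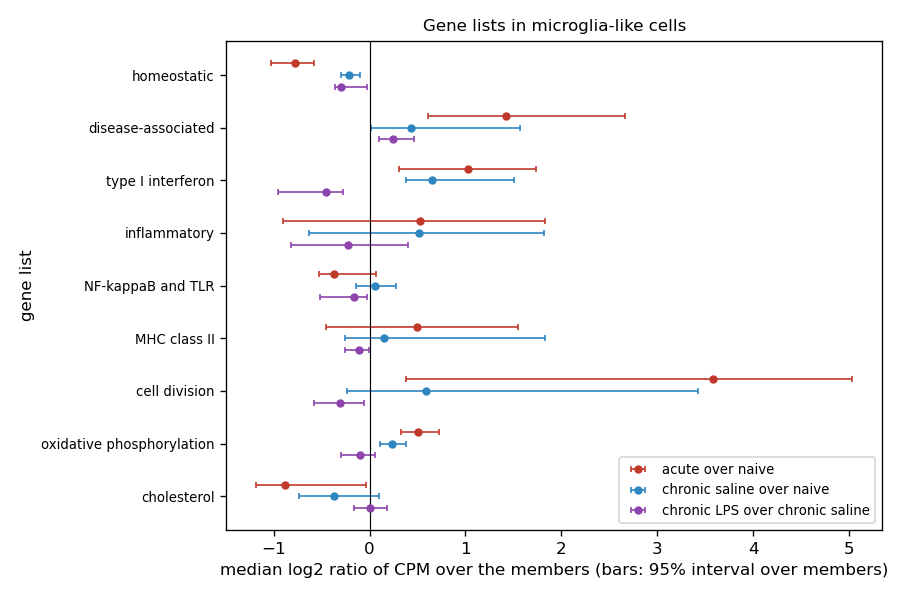
Median log2 ratio of CPM (horizontal axis) over the members of 9 gene lists (vertical axis) in microglia-like cells, for 3 comparisons of single libraries; bars are 95% intervals over the members. Interferon genes lie above 0 in acute over naive (1.03) and chronic saline over naive (0.65), and below 0 in chronic LPS over chronic saline (-0.45).

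Acute injury was compared with the naive cord to describe the microglial response 8 days after the cut. Microglia-like cells of the acute library (12126 against 3070 cells, 60759119 against 12232753 UMIs) had far higher levels of phagocytic and lipid-handling genes and lower levels of homeostatic genes. Gpnmb stood at 1205 against 32.1 CPM (37.6-fold; log2 5.23, 5.09 to 5.38), Spp1 at 1977 against 92.2 (21.4-fold) and Igf1 at 711 against 76.9 (9.24-fold). P2ry12 stood at 1032 against 2810 CPM (2.72-fold lower) and the fractalkine receptor Cx3cr1 at 1871 against 3812 (2.04-fold lower). Of 28 interferon genes 14 and of 19 cell division genes 12 were at least 2-fold higher, and of 18 cholesterol genes 8 were at least 2-fold lower and 3 higher.

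Of 25 disease-associated genes, 15 were at least 2-fold higher, 9 lay between, 1 was left open by its bound and none was 2-fold lower (median 1.43, 0.61 to 2.66). Besides those above, Lgals3 was 28.0-fold, the beta-glucan receptor Clec7a 22.4-fold, the phagocytic receptor kinase Axl 18.1-fold, the lysosomal Cd68 5.56-fold and Apoe 3.84-fold higher (19688 against 5124 CPM). Outside the list, the membrane-binding Anxa2 was 29.6-fold and Odc1 12.5-fold higher. In the naive library another class has at least 5-fold more of Lgals3 (neutrophil-like), Clec7a and Axl (border-associated macrophage-like), Cd68 (monocyte or macrophage-like), Anxa2 and Odc1 (fibroblast or mural-like). Of 22 homeostatic genes, 6 were at least 2-fold lower, 15 between and 1 left open by its bound (median -0.78, -1.03 to -0.57). P2ry13 was 2.54-fold, the selectin ligand Selplg 2.41-fold and Cst3 nearly 2-fold lower (log2 -0.97). Other lowest genes were Zfp36 (3.49-fold), the semaphorin Sema4a (2.84-fold), the cyclooxygenase Ptgs1 (2.77-fold), Dctd, a deaminase of nucleotide synthesis (2.75-fold), Msmo1, an enzyme of cholesterol synthesis (2.63-fold), the junction protein F11r (2.60-fold) and Eva1a (2.47-fold).

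Of 28 interferon genes, 14 were at least 2-fold higher, 13 between and 1 left open by its bound (median 1.03, 0.31 to 1.73). Ifi27 was 2.31-fold higher (298 against 129 CPM), Oas1a 9.48-fold (7.75 against 0.817 CPM, at least 5-fold higher in neutrophil-like cells of both libraries) and Bst2 level at 1.14-fold. Of 19 cell division genes, 12 were at least 2-fold higher and 7 between (median 3.58, 0.38 to 5.03, with 7 at the floor). The tubulin regulator Stmn1 was 33.2-fold higher (62.5 against 1.88 CPM) and the topoisomerase Top2a at least 82.1-fold, with no naive UMI. A group of 77 acute cells (0.635%), which formed a cluster led by Top2a when the library was clustered alone, held 77.9% of the acute Top2a UMIs and 33.9% of those of the list. Without these cells the list median was 2.37. Of 20 inflammatory genes, 8 were higher and 4 lower (median 0.52, -0.91 to 1.82); the chemokines Cxcl16 (2.29-fold) and Ccl7 (at least 18.4-fold) were among the higher. Of 18 cholesterol genes, 8 were at least 2-fold lower and 3 higher (median -0.88, -1.18 to -0.04), with the exporter Abca1 4.43-fold higher. MHC class II genes went both ways, with 6 of 13 at least 2-fold higher, 1 lower and a median of 0.50 (-0.46 to 1.55). RT1-Ba (3.17-fold) and RT1-Db1 (2.95-fold) were higher, both at least 5-fold higher still in border-associated macrophage-like cells. Cluster 7, with 7.16% of acute and 2.35% of naive microglia-like cells and no microglial marker among its leading genes, held 91.9% and 93.7% of their acute UMIs. Without it their ratios were 1.85 and 1.70 and the list median -0.16. Ctss, which trims the invariant chain, was 1.81-fold lower. The NF-kappaB and Toll-like receptor list had a median of -0.37 (-0.53 to 0.07), with Tlr2 1.97-fold lower.

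The median over all 9091 genes was -0.24, and all of these values are relative to the class total. Oxidative phosphorylation genes had a median of 0.50 (0.33 to 0.73) and mitochondrial transcripts 0.67 (0.21 to 0.82), the latter moving with the disease-associated and cell division genes. Markers of monocytes (median 0.72, 6 of 14 at least 2-fold higher) and of myelin (0.37, 4 of 10 higher; Mbp 31.9 against 3.27 CPM, at least 5-fold higher in fibroblast or mural-like cells) also moved with them. No single cluster held most acute cells: clusters 2, 4, 8, 1 and 0 held 20.8%, 19.5%, 17.4%, 16.8% and 15.2%, against 50.5% in cluster 0 for naive cells. Cluster 8, led by Spp1, Igf1 and Gpnmb and the deepest microglia-like cluster (median 9519 UMIs), held 2105 acute and 9 naive cells. Without it the disease-associated median was 0.84, the homeostatic -0.47, cell division 1.80 and MHC class II 1.13 (from 0.50; but 0.19 in thinned cells and -0.02 over members with at least 50 UMIs), and the ratios were 22.6 for Gpnmb, 14.0 for Anxa2, 6.58 for Odc1, 3.36 for Igf1, 3.32 for Cd68 and 2.46 for Apoe. Thinning to 1000 UMIs gave a homeostatic median of -0.46 and a cell division median of 0.98. The stricter cell filter gave ratios of 21.6 for Gpnmb, 15.9 for Anxa2, 6.04 for Odc1 and 5.20 for Igf1. Most cells of cluster 8 (median mitochondrial share 5.93%) are over that filter's mitochondrial limit and are left out by it.

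Positive evidence for the class of cluster 8 is weak. Its cells in the acute library held 253 CPM of P2ry12 and 102 of Sall1, a transcription factor of microglia, against 1468 and 255 in the other microglia-like clusters. These levels are above those of monocyte or macrophage-like (89.9 and 11.2 CPM) and border-associated macrophage-like cells (207 and 18.3 CPM) but not above those of neutrophil-like cells (582 and 127 CPM), which should lack both genes. Of the monocyte or macrophage markers, Ccr2 stood at 0.0916 CPM against 124 in monocyte or macrophage-like cells and Ly6c at 0.458 against 1034. Lyz2 stood at 1760 CPM against 14573, Plac8 at 211 against 6532 and Clec4a1 at 42.0 against 393, each lower than in the other microglia-like clusters too (2044, 416 and 61.5). Ms4a4a stood at 92.8 (4.65 in the other microglia-like clusters, 367 in border-associated macrophage-like and 0 in monocyte or macrophage-like cells). F13a1, low throughout, was also higher in the cluster. Over all libraries it stood at 3.64 CPM in cluster 8 and 2.70 in cluster 7, against at most 0.415 in any other microglia-like cluster. In the LPS library the cluster held 255 CPM of P2ry12 and 69.3 of Sall1, above neutrophil-like cells (136 and 22.4 CPM). Against border-associated macrophage-like cells (241 and 30.5 CPM) it was above for Sall1 alone, since the intervals of P2ry12 overlap. It held 9848 CPM of Lyz2 against 2487 in the other microglia-like clusters and 19495 in monocyte or macrophage-like cells.

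In border-associated macrophage-like cells (112 acute, 175 naive), the acute library had more Fabp4, a fatty acid carrier (122 CPM against no UMI, at least 60.4-fold), Spp1 (37.7-fold), Gpnmb (11.8-fold), Pla2g7 (8.32-fold) and fibronectin Fn1 (273 against 36.3 CPM). Spp1 is at least 5-fold higher in microglia-like and Pla2g7 in neutrophil-like cells of both libraries. MHC class II genes were lower (median -1.10, -1.23 to -0.68; 8 of 12 at least 2-fold), among them RT1-Bb (2.38-fold) and RT1-Db1 (2.35-fold). Il6st (3.15-fold), Selplg (2.79-fold) and Cst3 (2.33-fold) were lower as well, the last 2 at least 5-fold higher in acute microglia-like cells and Il6st in acute fibroblast or mural-like cells.

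Chronic saline was compared with naive to describe what differed 60 days after the cut. The saline animals had also been injected 3 days before collection, and the labels give no injection for naive animals. The design does not part the cut from the injection. In microglia-like cells of the saline library 11 of 24 phagocytic and 11 of 27 interferon genes were at least 2-fold higher, and all 21 homeostatic genes lay within 2-fold. Markers of monocytes (median 1.47) and neutrophils (1.23) were higher beside them. Gpnmb and Spp1 had smaller ratios over naive than in the acute library, whereas Ccl4 and Ccl7 had larger ones. Axl stood at 105 against 11.2 CPM (9.35-fold), Gpnmb at 266 against 32.1 (8.30-fold), Spp1 at 561 against 92.2 (6.08-fold) and Ccl4 at 194 against 32.1 (6.03-fold). The complement gene C4a was 2.95-fold higher, at 203 against 68.8 CPM.

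Of 24 disease-associated genes, 11 were at least 2-fold higher, 1 lower and 12 between (median 0.43, 0.01 to 1.57), with Clec7a 11.6-fold and Apoe 2.15-fold higher; naive border-associated macrophage-like cells have at least 5-fold more Axl and Clec7a than microglia-like ones. Of 27 interferon genes, 11 were at least 2-fold higher and 16 between (median 0.65, 0.38 to 1.51): Cxcl10, a T cell chemoattractant, was 7.93-fold and Ifit3 6.84-fold higher. Slfn4, not on the list, was 4.98-fold higher; it and Ifit3 are at least 5-fold higher in neutrophil-like cells. Of 17 inflammatory genes, 7 were higher and 3 lower (median 0.52, -0.64 to 1.82), with Ccl7 at least 81.5-fold higher at 20.0 CPM. All 21 homeostatic genes lay within 2-fold (median -0.21, -0.30 to -0.10). Cholesterol genes had a median of -0.38 (-0.73 to 0.10), with 17 of 18 within 2-fold. Hmgcs1 (1.84-fold), Cyp51 (1.70-fold) and Msmo1 (1.59-fold) of the synthesis pathway were lower, beside Chst2 (1.61-fold), Acsl3 (1.58-fold), the alarmin Il33 (1.56-fold), Cnp (1.54-fold), Cped1 (89.1 against 134 CPM), Il7r and Fez2 (both 1.49-fold) and Wasf2 (1.44-fold). The NF-kappaB list stood at 0.06, with all 22 within 2-fold, and cell division at 0.59 (-0.23 to 3.42; 7 of 14 higher, 1 lower).

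RT1-Db1 (3.63-fold), RT1-Ba (3.56-fold), RT1-Bb (3.56-fold) and RT1-Da (2.94-fold) of MHC class II were higher in the saline library, each at least 5-fold higher again in border-associated macrophage-like cells; the list had a median of 0.15 (-0.26 to 1.83). When each library was clustered alone, these genes were lower instead (log2 -2.37, -1.17, -2.69 and -1.81) and the list median was -0.60. Cluster 7, with 4.04% of saline microglia-like cells, held 91.8% to 97.0% of their saline UMIs, and without it the log2 ratios were -0.08, 1.01, 0.29 and 0.45. Markers of other cells moved with these groups: the median was 1.47 for monocyte markers (5 of 8 at least 2-fold higher), 1.23 for neutrophil markers (3 of 5), 0.50 for myelin and oligodendrocyte markers (3 of 8 higher, 1 lower, with an interval that spans 0) and 1.05 for acute phase genes (5 of 9), and the last was -0.06 in thinned cells. The dissociation list stood at 0.29 (2 of 16 higher, among them Egr1 at 2.09-fold) and mitochondrial transcripts at 0.11. Cluster 0 held the largest part of the class in both libraries, 50.5% of naive and 40.8% of saline cells, and the median over all 7454 genes was -0.04.

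In border-associated macrophage-like cells (73 saline, 175 naive), Lgals1 was 9.96-fold, Gpnmb 4.33-fold and the calcium-binding S100a6 3.71-fold, S100a11 2.51-fold and S100a4 2.17-fold higher in the saline library. The class held 62 saline and 163 naive cells at resolution 2, and whether cells of another type add to these saline levels was not tested. Cxcl13 (3.26-fold), RT1-CE1 (2.17-fold), Gda (1.77-fold), Bst2 (1.48-fold) and Anxa3 (1.41-fold) were lower. Interferon genes, whose median was 0.65 in microglia-like cells, had a median of -0.21 (-0.47 to -0.03) there, with 5 of 25 at least 2-fold lower and 1 higher.

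Chronic LPS was compared with acute to set the stimulated chronic state beside the early response. The labels give no injection for acute animals, so the design does not part time since the cut from the LPS injection. Microglia-like cells of the LPS library had at least 2-fold less of 6 of 25 phagocytic, 9 of 28 interferon and 13 of 19 cell division genes, and 21 of 22 homeostatic genes lay within 2-fold. Gpnmb stood at 429 against 1205 CPM (2.81-fold lower), Spp1 at 1042 against 1977 (1.90-fold lower) and Tmem119, a membrane protein of homeostatic microglia, at 361 against 204 (1.77-fold higher). Complement C3 was 1.64-fold higher (1040 against 633 CPM) and Ccl5 8.09-fold (16.8 against 2.07 CPM).

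Of 25 disease-associated genes, 6 were at least 2-fold lower and 19 between (median -0.68, -0.93 to -0.29), with Axl 2.35-fold, Lgals3 2.12-fold and Igf1 1.87-fold lower. Of 28 interferon genes, 9 were at least 2-fold lower and 19 between (median -0.73, -1.04 to -0.40), with Ifitm3 8.65-fold, Oas1a 4.13-fold and Ifi27 2.06-fold lower; Oas1a and Ifitm3 are at least 5-fold higher in neutrophil-like cells of the LPS library. Of 19 cell division genes, 13 were at least 2-fold lower (median -2.01, -2.58 to -0.83), among them the ribonucleotide reductase subunit Rrm2 (16.8-fold), Top2a (11.8-fold) and Stmn1 (3.43-fold). Anxa2, Rrm2 and Top2a are at least 5-fold higher in neutrophil-like and Stmn1 in fibroblast or mural-like cells of the LPS library. Of 22 homeostatic genes 21 lay within 2-fold and 1 was left open by its bound (median 0.31, 0.20 to 0.45). The other lowest genes were Anxa2 (2.85-fold), Ms4a6bl (2.35-fold), Cd68 (1.92-fold) and the tetraspanin Cd63 (1.68-fold). The other highest were Ctnnbl1 (1.74-fold), the butyrate receptor Hcar2 and Lyz2 (both 1.69-fold), Il7r and the immediate early gene Fos (both 1.65-fold), Selplg (1.58-fold), and Jun and Susd3 (both 1.57-fold). Cholesterol genes had a median of 0.38 (0.03 to 0.64; Idi1 1.63-fold higher), oxidative phosphorylation -0.36 (-0.46 to -0.19), NF-kappaB 0.21 (0.01 to 0.33) and inflammatory genes 0.03 (3 of 20 higher, 1 lower).

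Neutrophil markers had a median of 1.77 (5 of 9 at least 2-fold higher) and lymphocyte markers 1.89 (8 of 11 higher, 3 at the floor) in LPS against acute microglia-like cells, and mitochondrial transcripts -0.33 (-0.42 to -0.26). Without the 77 acute cells led by Top2a the cell division median was -1.09. Without cluster 8 the homeostatic median was 0.05, the disease-associated -0.41, the interferon -0.48, the cell division -0.31 and the MHC class II median -0.17 in place of 0.10, and Ms4a6bl was 1.34-fold lower. Cluster 1 held the largest part of LPS cells (32.3%) and cluster 2 of acute cells (20.8%), and the median over all 10021 genes was 0.05.

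Acute was compared with chronic saline to set the early against the late injured cord. The labels give no injection for acute animals, so the design does not part time since the cut from the saline injection. Disease-associated genes were higher in acute microglia-like cells, 9 of 25 at least 2-fold and 1 lower (median 0.92, 0.50 to 1.31). Lpl was 5.60-fold, Gpnmb 4.53-fold, Lgals3 3.62-fold, Spp1 3.53-fold and Igf1 3.52-fold higher. Anxa2 (9.19-fold), Odc1 (4.47-fold), Cd68 (2.48-fold), the protease inhibitor Cstb (2.12-fold), Ms4a6bl (1.97-fold) and Cd63 (1.90-fold) were also higher. In the saline library neutrophil-like cells have at least 5-fold more Anxa2 and Lgals3 than microglia-like cells, and monocyte or macrophage-like cells more Cebpb and H3f3c. P2ry12 stood at 1032 against 2488 CPM (2.41-fold lower), and the 22 homeostatic genes had a median of -0.61 (-0.81 to -0.45), with 1 of the 21 whose ratio has a direction at least 2-fold lower. Zfp36 (4.42-fold), RT1-CE2 (2.60-fold), H3f3c (2.40-fold), Dctd (2.30-fold), F11r (2.22-fold), Cebpb (2.20-fold), Ch25h (2.16-fold), Pdia4 (2.15-fold) and Ptgs1 (2.09-fold) were lower in the acute library.

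In this comparison, genes with so few saline UMIs that their bound has no direction are left out of the counts but kept in the medians. Of 27 interferon genes, 4 were at least 2-fold higher and 1 lower (median over 28 genes 0.06, -0.11 to 0.36). Of 19 inflammatory genes, 6 were at least 2-fold lower and 3 higher (median over 20 genes -0.46, -1.16 to 0.57, and -0.35 without the gene left out), with Ccl7 4.43-fold and Ccl4 1.48-fold lower. NF-kappaB genes had a median of -0.33 (-0.77 to -0.16), with Tlr2 1.73-fold lower, and MHC class II genes -0.19 (-0.55 to -0.01). Cholesterol genes stood at -0.40 (-0.51 to -0.04). Of 19 cell division genes, 12 were at least 2-fold higher (median 1.71, 0.53 to 2.80; Stmn1 62.5 against 20.2 CPM). Neutrophil markers had a median of -2.03 (4 of 6 at least 2-fold lower) and mitochondrial transcripts 0.57 (0.03 to 0.75), and the median over all 7472 genes was -0.17. Without the 77 acute cells led by Top2a the cell division median was 0.65. Without cluster 8 it was 0.15, the disease-associated 0.50, the homeostatic -0.34 and the MHC class II median 0.03, and the ratios were 4.96 for Anxa2, 1.74 for Igf1, 1.58 for Cd68 and 1.02 for Ms4a6bl. In thinned cells the cell division median was -0.12, the homeostatic -0.29, and the ratios of Odc1 1.75 and of Igf1 2.30. The stricter cell filter, which leaves out most cells of cluster 8, gave ratios of 2.72 for Gpnmb, 5.85 for Anxa2 and 2.33 for Odc1. Cluster 2 held the largest part of acute cells (20.8%) and cluster 0 of saline cells (40.8%).

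To see whether LPS and acute injury go with differences in the same microglial genes, the ratios of LPS over saline and of acute over naive, which share no library, were set side by side. The 2 ratios are still not free of a common technical difference. Median ribosomal protein shares were 12.9% (acute) and 13.7% (LPS) against 8.50% (naive) and 9.98% (saline). In the same order, doublet removal took out 1687 and 713 cells against 1 and 3. Cluster 14 held 0.520% and 0.504% of microglia-like cells against 11.2% and 10.0%. Across 7454 genes with at least 50 UMIs in each library, Pearson's r was 0.44 and Spearman's rho 0.47; genes are not independent replicates, so no p-value is given. Of the 100 highest genes in each comparison, 23 were shared, against 1.34 for independent lists, and of the 100 lowest, 17. Odc1, Igf1, Spp1, Gpnmb, Lgals3 and Apoe were higher in both, and P2ry12, Zfp36 and Ch25h lower in both. In thinned cells, however, the LPS over saline ratio was 1.02 for Gpnmb, 1.20 for Igf1 and 1.56 for Odc1, so Gpnmb was level there. Thinning also leaves out cells under 1000 UMIs, and the stricter cell filter, which does not equalise depth, gave 1.01 for Gpnmb. The move of Gpnmb therefore cannot be put down to depth alone. Slfn4, an interferon-responsive gene, was higher in acute than naive and lower in LPS than saline cells. In border-associated macrophage-like cells r was 0.18 over 1782 genes, where microglia-like cells brought to the same depth gave 0.30, and in cells thinned to 1000 UMIs r was 0.22. Without cluster 14, whose share differs in both comparisons, r was 0.41.

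**Figure D3:**
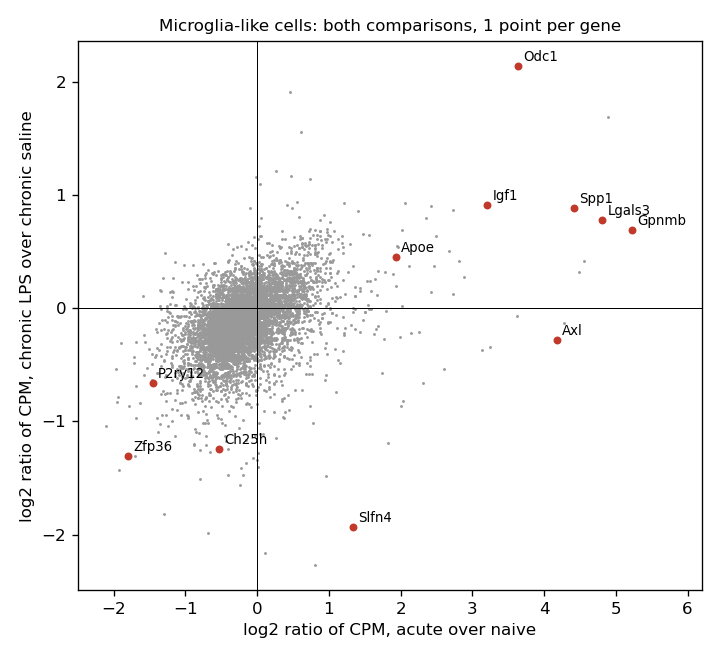
Each point is a gene in microglia-like cells with at least 50 UMIs in every library, placed by its log2 CPM ratio of acute over naive (horizontal axis) and of chronic LPS over chronic saline (vertical axis). Pearson's r over the 7454 genes is 0.44, and Odc1, Igf1, Spp1, Lgals3, Gpnmb and Apoe lie above 0 on both axes; cells are not thinned here, and in thinned cells Gpnmb was level between LPS and saline.

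The series asks about diverse microglial states, so the spread of the main genes over single cells was measured after thinning each cell to 1000 UMIs. Thinning left out 340 naive, 150 acute, 116 saline and 74 LPS microglia-like cells. P2ry12 was seen in 91.5% (90.4 to 92.5) of naive, 65.4% (64.6 to 66.3) of acute, 87.6% (85.4 to 89.6) of saline and 77.4% (76.4 to 78.3) of LPS cells. Spp1 was seen in 1.72% (1.27 to 2.28), 21.3% (20.6 to 22.1), 6.51% (5.06 to 8.22) and 8.28% (7.68 to 8.92) in the same order, and Gpnmb in 0.879%, 21.5%, 6.11% and 6.85%. Igf1 was seen in 5.90%, 20.3%, 11.4% and 11.8%. Neutrophil-like cells, which should lack these genes, gave 6.90%, 18.5%, 8.79% and 7.79% for P2ry12, 0%, 3.70%, 0% and 0% for Spp1, 3.45%, 14.8%, 1.10% and 0% for Gpnmb, and 0%, 0%, 1.10% and 0.649% for Igf1. The naive shares of Spp1, Gpnmb and Igf1 and the acute share of Gpnmb lie within the intervals of this background (up to 11.9%, 17.8%, 11.9% and 33.7%) and these shares cannot be told from it, and the interval of the saline Gpnmb share (4.70 to 7.77) overlaps that of its background (up to 5.97%). The acute level of Gpnmb is above it, at 1205 CPM over the class and 368 outside cluster 8 against 90.9 (43.6 to 167) in neutrophil-like cells. Median depths before thinning were 3722.5, 3530.5, 4220 and 3053 UMIs in microglia-like and 3758, 3646, 5035 and 6368.5 in neutrophil-like cells. Without thinning, P2ry12 was seen in 98.1%, 92.2%, 96.5% and 95.1% of microglia-like cells, Spp1 in 3.00%, 37.5%, 11.9% and 13.7%, Gpnmb in 1.92%, 33.9%, 11.4% and 11.1%, and Igf1 in 19.1%, 38.8%, 27.9% and 24.7%.

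Across thinned cells of the acute library, the homeostatic and disease-associated sums ran against each other, with a Spearman correlation of -0.55, against 0.11 in naive, -0.20 in saline and -0.19 in LPS cells. Cst3 gave 82.1% of the acute homeostatic UMIs, and without it and Apoe the correlations were -0.53 in acute, -0.13 in naive, -0.31 in saline and -0.28 in LPS cells. Disease-associated and MHC class II sums had a correlation of -0.49 in acute cells (0.03 naive, -0.19 saline, -0.08 LPS), but Ctss gave 80.5% of the acute MHC class II UMIs, and without it and Apoe the correlation was -0.07. Cluster 7 had high levels of both groups (Gpnmb 1409, Spp1 4072 and Cd74 4971 CPM). Interferon and inflammatory sums had correlations of 0.02, 0.05, 0.02 and 0.02 in naive, acute, saline and LPS cells. Without thinning these were 0.30, 0.41, 0.35 and 0.25, and the negative correlations above turned positive (0.29, 0.62 and 0.50 for homeostatic and disease-associated sums in acute, saline and LPS cells, 0.42, 0.59 and 0.56 for disease-associated and MHC class II sums). At least 3 UMIs of interferon genes were found in 4.14% of naive, 9.42% of acute, 6.11% of saline and 4.94% of LPS cells, and in 58.6%, 63.0%, 40.7% and 43.5% of neutrophil-like cells, which express them. Without thinning these shares were 40.0%, 50.9%, 49.7% and 33.6% of microglia-like cells.

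**Figure D4:**
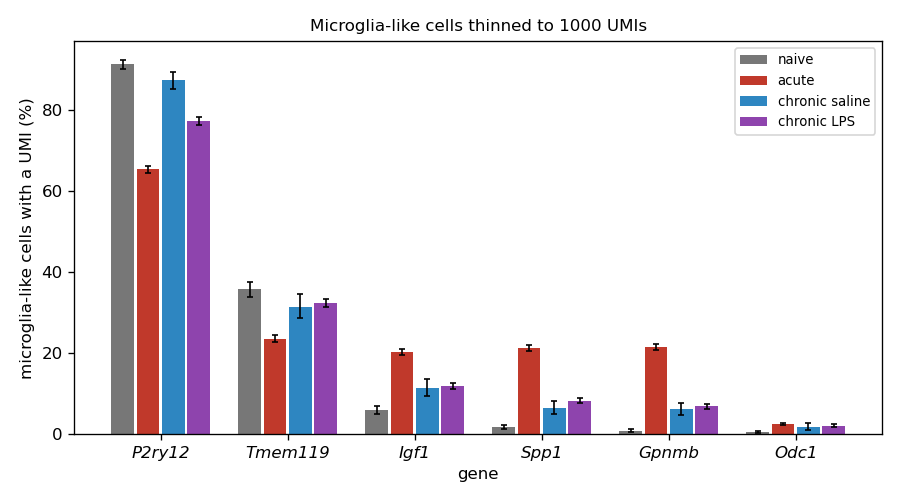
Share of microglia-like cells with at least 1 UMI (%, vertical axis) of 6 genes (horizontal axis) after thinning each cell to 1000 UMIs, for the 4 libraries, with exact 95% binomial intervals as bars. P2ry12 is lowest and Igf1, Spp1 and Gpnmb are highest in the acute library.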

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

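The neutrophil tests and the border-associated macrophage test of the interferon pattern, and the border-associated macrophage test of the 10 lowest genes, were chosen only after the result was seen. Several results were picked out because 2 cell classes went opposite ways in the same comparison of libraries. The difference between classes was not tested, since each group has 1 library. Interferon genes with LPS against saline had a median log2 ratio of 0.24 in border-associated macrophage-like and -0.45 in microglia-like cells, and with saline against naive 0.65 in microglia-like and -0.21 in border-associated macrophage-like cells. Both comparisons use the saline library, so they are not independent, and a trait of that library alone could give both. MHC class II genes in acute against naive stood at 0.65 in monocyte or macrophage-like and -1.10 in border-associated macrophage-like cells. In LPS against acute, homeostatic genes stood at 0.31 in microglia-like and -0.70 in monocyte or macrophage-like cells. Complement and Fc receptor genes stood there at 0.26 in border-associated macrophage-like and -0.43 in monocyte or macrophage-like cells, and cholesterol genes at 0.38 in microglia-like and -0.55 in border-associated macrophage-like cells.

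Haemoglobin transcripts, which were left out of the named genes and enter the comparisons through the erythroid marker list alone, were picked out because over all barcodes they stood at 599 CPM in the acute and 1604 CPM in the LPS library, above 3.83 CPM in the naive and 15.2 CPM in the saline library. This difference was not tested either.

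The ratios of LPS over saline and of acute over naive went together across microglial genes, with Pearson's r at 0.44. Mitochondrial and ribosomal protein genes are argued against as the points that carry r, since r over the 7363 genes left without them was 0.42. Few genes were left out, so this does not address the difference in ribosomal protein share between the libraries. Without the shallow cluster 14, a setting chosen only after the result was seen, r was 0.41. Unequal depth cannot be told apart, since r in cells thinned to 1000 UMIs was 0.22, which is 50.0% of the main value and 73.4% of the 0.30 found with whole cells brought to the same totals. A difference between libraries that acts on every class alike cannot be told apart either: r in border-associated macrophage-like cells was 0.18, which is 60.2% of the microglial 0.30 at that depth. A shared microglial response to LPS and to injury may add to the rest, as a hypothesis that these 4 libraries do not settle. A difference in preparation or filtering is as open, since doublet removal set the acute and LPS libraries together against naive and saline.

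Interferon genes were lower in LPS than in saline microglia-like cells, with a median of -0.45. Neutrophil transcripts are argued against for the 15 of 27 members that are no higher in saline neutrophil-like than in saline microglia-like cells. Their median was -0.36 (-1.19 to -0.22). These members were picked partly by their saline microglia-like level, which is the denominator of the ratio. This choice can by itself favour a lower median. The 12 others, picked the other way, had a median of -0.45 (-0.96 to -0.26). For these 12, neutrophil transcripts cannot be told apart. The limit that S100a9 sets (0.0356% of the excess of summed interferon CPM) assumes that background removal left S100a9 in place. A difference that acts on every class alike is argued against by the border-associated macrophage-like median of 0.24, although neutrophil-like cells went the same way as microglia-like cells (-0.98). A few cells with high levels cannot be told apart as the source, since the median without the highest 5% of cells in each library was -0.25, with an interval (-0.40 to 0.04) that reaches 0. An interferon response that is weaker 3 days after LPS than after saline may remain, but with 1 library per group a difference between animals is as open.

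The 10 genes lowest with LPS against saline in microglia-like cells had a median of -1.26. Unequal depth is argued against, since their median in thinned cells was -1.22. A difference between libraries that acts on every class alike could account for most of them. Their median in border-associated macrophage-like cells was -0.95 and 9 of 10 were lower there, Cebpb with an interval that includes 0. Ccl4 was higher there (log2 0.50, 0.09 to 0.93). Slfn4, Zfp36 and Ch25h are therefore open to handling, to the animals and to LPS acting on all myeloid cells, and the design does not part these.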

How the results depend on the processing

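The settings without the Gpnmb-led cluster, without the shallow cluster, without the Cd74-rich cluster, without the Top2a-led acute cells, without members whose bound has no direction and without the most abundant member were chosen only after the result was seen; all others were set beforehand. A change of direction was counted only where the interval of the main value leaves out 0. Of 1740 list medians recomputed, 1701 stayed within their interval, 35 moved beyond it and 4 changed direction. Of 1300 gene ratios the numbers were 854, 441 and 5, of 120 shares of cells of a class 83, 37 and 0, of 144 single-cell values 32, 93 and 19, and of 8 values across genes 5, 3 and 0. Whatever the interval, 132 list medians and 24 of 72 correlations across cells took the other sign. Without members whose bound has no direction, every list median stayed within its interval. No paired analysis was possible because each group has 1 library and the labels pair none of them. The cause of these differences was not tested, except that the thinned setting holds depth equal.

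With the stricter cell filter the microglia-like share was 89.2% naive, 96.1% acute and 89.6% LPS (from 87.5%, 94.5% and 88.7%), the acute monocyte or macrophage-like share 0.779% (from 0.499%), and the neutrophil-like share 0.390% acute, 8.66% saline and 2.43% LPS (from 0.226%, 6.68% and 1.79%). The disease-associated median for LPS over saline was 0.0474 (from 0.24), and the homeostatic median -0.50 in acute over naive (from -0.78), 0.14 in LPS over acute (from 0.31) and -0.35 in acute over saline (from -0.61). The filter's 5% mitochondrial limit removes most cells of the Gpnmb-led cluster (median share 5.93%) and of the Cd74-rich cluster (median share 5.17%). Keeping called doublets gave an acute microglia-like share of 95.3%, and clustering at resolution 2 gave 98.1% acute and 90.7% LPS.

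With each library clustered alone the microglia-like share was 94.1% acute and 79.2% saline (from 94.5% and 81.8%), the border-associated macrophage-like share 1.36% acute and 7.70% saline (from 0.873% and 5.36%), and the acute monocyte or macrophage-like share 0.00%. The MHC class II median for saline over naive was -0.60 (from 0.15), and RT1-Db1, RT1-Ba, RT1-Bb and RT1-Da changed direction to -2.37, -1.17, -2.69 and -1.81.

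With median-ratio scaling the MHC class II median for LPS over saline changed direction from -0.11 to 0.0033, and the homeostatic median was -0.54 in acute over naive and -0.44 in acute over saline. The mean over cells gave a homeostatic median of 0.11 in LPS over acute. In cells thinned to 1000 UMIs the disease-associated median was 0.0873 for LPS over saline. The homeostatic median was then -0.46 in acute over naive, 0.11 in LPS over acute and -0.29 in acute over saline. Acute phase genes changed direction in saline over naive (1.05 to -0.0587), and cell division genes in acute over saline (1.71 to -0.12).

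Without the Gpnmb-led cluster the homeostatic median was -0.47 in acute over naive, 0.0501 in LPS over acute and -0.34 in acute over saline. MHC class II stood at -0.17 in LPS over acute (from 0.10) and changed direction in acute over saline (-0.19 to 0.0311), and cell division stood at -0.31 in LPS over acute (from -2.01) and 0.15 in acute over saline (from 1.71). Without the Cd74-rich cluster RT1-Db1 changed direction in saline over naive (1.86 to -0.0798). Over genes with 200 or more UMIs in each library, Pearson's r was 0.52 and Spearman's rho 0.54 (from 0.44 and 0.47).

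Correlations of list sums across cells changed direction without thinning, where deeper cells hold more of every list. In the order naive, acute, saline, LPS, homeostatic and interferon sums went from -0.04, -0.12, -0.13 and -0.03 to 0.48, 0.21, 0.41 and 0.26, and homeostatic and inflammatory sums from -0.10, -0.13, -0.06 and -0.09 to 0.37, 0.18, 0.33 and 0.21. In the order acute, saline, LPS, homeostatic and disease-associated sums went from -0.55, -0.20 and -0.19 to 0.29, 0.62 and 0.50, and disease-associated and MHC class II sums from -0.49, -0.19 and -0.08 to 0.42, 0.59 and 0.56. Without the most abundant member of each list, the naive correlations of homeostatic sums changed direction to -0.13 with disease-associated (from 0.11), 0.0079 with interferon and 0.0252 with inflammatory sums. So did that of homeostatic and interferon sums in LPS cells (0.0089) and of disease-associated and MHC class II sums in saline cells (0.0214).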

Other observations

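Monocyte or macrophage-like cells, few in number (108 naive, 64 acute, 49 saline, 115 LPS), were compared between the acute library and 2 others. Of 20 disease-associated genes, 8 were at least 2-fold higher in acute than naive cells, 12 lay between and none was 2-fold lower (median 0.57, 0.24 to 1.73). Against naive, the chemokine Ccl24 stood at 273 CPM with no naive UMI (at least 50.8-fold), Cd63 was 43.9-fold, Spp1 at least 26.5-fold and Apoe 15.3-fold higher. In the acute library Cd63 and Spp1 are at least 5-fold higher in microglia-like, Apoe in border-associated macrophage-like and Il1b in neutrophil-like cells. Zfp36 (3.48-fold), Il1b (2.61-fold), Jup (2.34-fold) and Cebpb (1566 against 3063 CPM) were lower. MHC class II genes had a median of 0.65 (0.15 to 1.42), with 4 of 10 at least 2-fold higher. In the LPS library against acute, S100a8 (18.7-fold), S100a9 (17.3-fold), the haptoglobin gene Hp (210 against 52.4 CPM), all at least 5-fold higher in neutrophil-like cells, and Fcnb (2.80-fold) were higher, and Ccl24 (at least 47.0-fold), Apoe (23.5-fold), Tgm2 (13.1-fold) and Cst3 (5.71-fold, at least 5-fold higher in microglia-like cells) lower.

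Border-associated macrophage-like cells of the LPS library had 14.8-fold more Cxcl13, 4.30-fold more C3, 3.46-fold more S100a6, 3.01-fold more Pla2g2d and 2.58-fold more Adgre1 than those of the acute library. They had less Fabp4 (86.3-fold), Fn1 (12.5-fold), Spp1 (7.90-fold), Gpnmb (7.25-fold) and Pla2g7 (6.81-fold). Acute cells against saline cells had more Fabp4 (at least 33.3-fold), Fn1 (4.14-fold), Hmox1, which breaks down haem (3.75-fold), and the peroxiredoxin Prdx5 (3.23-fold). They had less S100a6 (7.61-fold), Ccr2 (4.07-fold), Myadm (3.96-fold), Zfp36 (3.84-fold) and Crip1 (3.17-fold). At resolution 2 the class held 62 saline and 109 acute cells, beside an NK cell-like cluster with Ccr2 and Crip1 among its leading genes. Whether such cells add to the saline levels was not tested. Spp1 is at least 5-fold higher in microglia-like cells, and S100a6, Fn1 and Pla2g7 in monocyte or macrophage-like cells of at least 1 of these libraries. The interferon median of acute over saline there was 0.51 (0.09 to 0.73) and the MHC class II median -0.83 (-1.29 to -0.29).

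Haemoglobin lay in few barcodes. Barcodes with 100 or more haemoglobin UMIs numbered 19 in the acute and 9 in the LPS library and 0 in the others. Of the 8381 haemoglobin UMIs in LPS microglia-like cells, 8288 lay in 1 cell, and of 5624 in acute ones, 2927 lay in 1 cell, with haemoglobin seen in 8 cells.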
